A study of Mus musculus with 7 samples.

How the data were processed

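Total RNA of sorted, reporter-positive pancreatic cells was measured on Affymetrix arrays in 7 mice, 3 weaned early and 4 suckling. Per the labels' protocols, the RNA of each mouse was prepared with a micro-scale column kit and amplified with the Ovation Pico System V2 before labelling, and each mouse was 1 biological repetition. Such amplification starts from small amounts of RNA and adds its own scatter between arrays, which a design with 1 array per mouse cannot separate from differences between mice.

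The deposited intensity values are 1 number per probe set and array, made by the authors with RMA in Partek 6.6, per the submitters' processing notes, which name the tools without their order or settings. The values range from 1.45 to 12755, which is a linear scale, so log2 was taken here before any other step. The array medians lie between 14.1 and 14.9, and how the authors brought the arrays to a common level beyond the name RMA is not given in the sources used here. RMA shares information between arrays, and shrinks differences of dim probe sets towards 0. All 7 value columns were used, and 0 per-sample columns were left out.

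Of 35556 probe sets, 21789 carry 1 gene symbol in the platform annotation, 1621 carry several and 12146 carry none. Symbols of 21698 single-gene probe sets were matched by gene ID to a RefSeq gene table of assembly GRCm38.p6, which was used only for gene names and for the order of genes. The array annotation used here names no genome build, so no coordinates are given. For the 999 genes with more than 1 probe set the probe set with the highest mean over all arrays stood for the gene, which left 19938 genes. No filter on dim genes was applied. As a background level, chosen after the data were seen, served the range of Xist and of Eif2s3y, Uty and Kdm5d on the 4 arrays each without their signal, 1.80 to 3.15 log2 units, which held both group means of 5 named genes and 1 group mean of 4. Genes without a single-gene probe set were not analysed here.

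The groups were compared gene by gene with limma (lmFit and eBayes, version 3.58.1, in R 4.3.3) on the log2 intensities, with no covariate, two-sided, and with Benjamini-Hochberg adjustment over all genes at a threshold of 0.05. Differences are weaned minus suckling. Shifts of 29 gene lists were tested with limma's camera at its preset correlation of 0.01, which assumes that list members are nearly independent, and adjusted over the 29 lists. The lists hold 786 genes, of which 709 were measured and 38 are in more than 1 list. They cover beta-cell transcription factors, maturation, immature or disallowed genes, secretory granule and exocytosis, cell cycle, G1 regulators, 6 metabolic pathways, glycolysis among them, the unfolded protein response, the prolactin and serotonin pathway, cytosolic ribosome, 5 secondary lists (immediate early and dissociation, glucocorticoid, circadian, interferon, sex-linked) and 9 lists of markers of other cells. A list's value is the median log2 difference of its measured members. Member counts are given over all genes and adjusted over the list alone. The means of lists per array were compared by exact two-sided permutation over all 35 splits of the arrays into 3 and 4.

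The design, the lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The rule for named genes took 12 genes in each direction, those past the threshold with groups that do not overlap and then those with the smallest p among named protein-coding genes. It also took up to 4 members of each list past the threshold, over all genes or else over the list alone, or otherwise the 2 members with the smallest p, and a fixed set of 25 beta-cell, cell cycle, metabolic and exocrine genes, of which 7 were not analysed here. Predicted genes, microRNA, small nucleolar RNA and olfactory receptor genes were counted and not named under the first part of the rule.

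The alternatives were an intensity trend with a robust prior, quantile normalization, centring of each array on its median, filters at the 25th percentile and the median of level, the mean of a gene's probe sets, array weights, covariates for the acinar, other-cell and immediate early list means, leaving out each array in turn, an adjusted threshold of 0.1, an unadjusted p under 0.05 with a 1.5-fold difference, camera with an estimated correlation, and fry. After the data were seen, a fit on all probe sets, the exact permutation of list means beyond those planned and a fit without suckling replicates 2 and 9 were added. That permutation had been planned for the lists of other cells and the immediate early list. Tests were run on simulated data with 200 of 19938 genes changed, in 20 draws. With 3 against 4 arrays, limma recovered 32.8% of genes changed 1.5-fold, 92.9% of those changed 2-fold and 99.9% of those changed 4-fold, and 6.21% of calls were unchanged genes. Noise was drawn as normal with limma's moderated variances, and the adjusted threshold is stricter where fewer genes change. These rates therefore do not carry over to the data, where Fggy at 5.32-fold and Gpx2 at 3.50-fold missed the threshold. A list shifted by 0.3 on the log2 scale was found in 100% of draws, with 0.15 other lists called per draw when a list that shares members was not counted, on simulated genes that vary independently. That shift is larger in size than the median of every list that passed in the data, acinar markers excepted. Smaller shifts were not simulated. Figures were drawn in Python 3.11.15.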

Results

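Gene expression was measured in beta cells of individual mice at postnatal day 25. In these mice an insulin-driven Cre recombinase had switched on a yellow fluorescent reporter at the Rosa26 locus, which marks insulin-producing cells for flow sorting. Of the 7 mice, all on the outbred ICR background, 3 had been weaned early at day 18 and 4 were still suckling. Between 2000 and 6000 fluorescent cells were collected per mouse, and each mouse gave 1 array. The sorted cells gave strong signal for beta-cell transcripts such as Ucn3, a hormone of mature beta cells (10.5 ± 0.20 log2 units, SD, n = 3 weaned, against 10.5 ± 0.12, n = 4 suckling). They also gave strong signal for Gcg, Sst and Ppy, which encode glucagon, somatostatin and pancreatic polypeptide, with suckling means of 12.1, 12.0 and 11.2 log2 units. The insulin gene Ins2 gave less signal, at 8.25 ± 0.24 log2 units in weaned and 8.27 ± 0.11 in suckling mice. Whether other cells among those sorted or a weak Ins2 probe set account for this was not tested. Median intensity ranged from 14.1 to 14.9 across the arrays and the highest intensity from 10033 to 12755. The correlation between arrays, taken across genes, which are not independent replicates, was 0.984 to 0.988 within a group and 0.980 to 0.988 between groups. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.14. The array descriptions carry the code L13 on the 3 weaned arrays and L14 on the 4 suckling arrays, so whatever the codes stand for cannot be told apart from weaning.

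The comparison of prematurely weaned with suckling mice addresses how gene expression in beta cells of the same age differs after early weaning. The design does not separate the change of food from other effects of weaning. Few single transcripts separated the groups. Hapln4, a link protein of the hyaluronan matrix (probe set 10572282), was 3.22-fold lower in weaned mice, at 5.20 ± 0.20 log2 units (SD, n = 3) against 6.88 ± 0.03 (n = 4). Its log2 difference was -1.69 (SE 0.12, adjusted p = 0.00249, limma). The long non-coding RNA AI506816 (probe set 10351504), named here because it passed the threshold although it lies outside the rule for named genes, was lower in weaned mice at 5.20 ± 0.52 against 7.27 ± 0.18 log2 units (-2.07, SE 0.22, adjusted p = 0.0315). Cstdc1, a cystatin-domain gene (probe set 10476906), was higher in weaned mice, at 3.92 ± 0.15 against 2.45 ± 0.20 log2 units (1.48, SE 0.14, adjusted p = 0.0146). The suckling level lies within 1.80 to 3.15, the range of Xist and Y-linked transcripts on arrays that lack their signal, so the size of this difference is a lower bound. In each of these 3 genes the groups of arrays did not overlap. Fggy, which encodes a carbohydrate kinase, had the widest difference among the genes next to the threshold, -2.41 (SE 0.28, adjusted p = 0.0511). Its 5 probe sets differed by -2.41, -2.42, -2.04, -2.27 and -0.35, of which -2.04 and -2.27 are bounds, since the weaned means of those probe sets (3.10 and 2.30) lie at background.

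By limma, 3 of 19938 genes passed an adjusted p of 0.05, 1 higher and 2 lower in weaned mice, and 7 passed 0.1. At an unadjusted p under 0.05 there were 1512 genes, where 997 are expected on average under chance and the other splits of the same arrays into 3 and 4 gave 654 to 1478. Of these 875 were higher and 637 lower in weaned mice, a split that became 1184 to 434 when each array was centred on its own median, which moved the median of all genes by 0.035. The groups did not overlap for 1460 genes, or 7.32%, where chance gives 5.71%. Without suckling replicates 2 and 9, an alternative chosen after the data were seen, 0 genes passed by limma and 482 were higher and 607 lower at an unadjusted p under 0.05. The differences of Hapln4 (-1.69), AI506816 (-2.10) and Cstdc1 did not shrink in that fit, which has fewer arrays. Hapln4 stayed past the threshold without any single array. Cstdc1 did so only without suckling replicate 2, and AI506816 only without weaned replicate 12, with adjusted p of 0.0227 to 0.127 and 0.0208 to 0.226 over the arrays left out and log2 differences of 1.41 to 1.56 and -2.27 to -1.78.

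**Figure D1:**
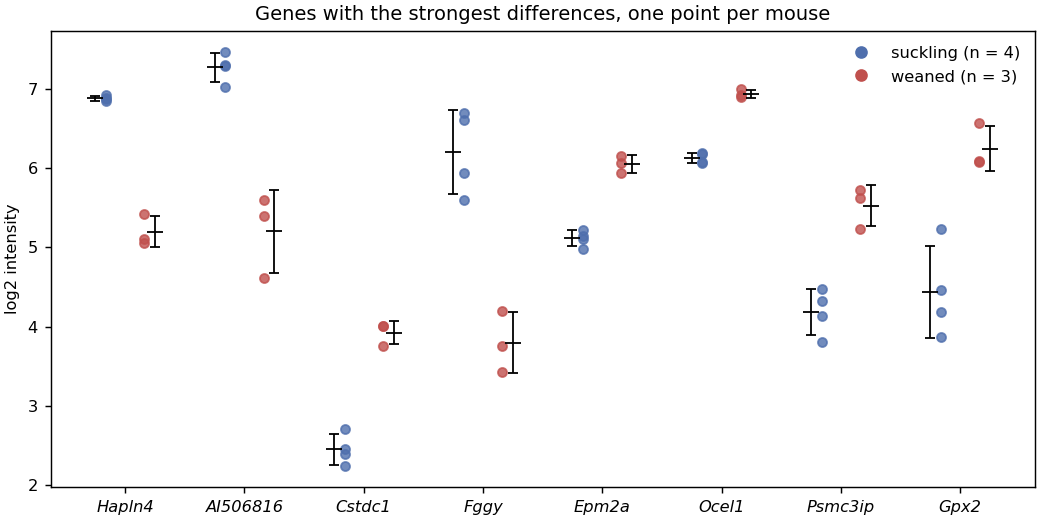
Log2 intensity (vertical axis) of 8 genes, the 3 past the threshold and 5 that missed it, on each of the 3 weaned and 4 suckling arrays, 1 point per mouse, with bars for mean and SD. Hapln4 lies between 5.06 and 5.42 on the weaned arrays and between 6.85 and 6.92 on the suckling arrays.

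The remaining genes with the smallest p values missed the threshold, and their differences are given as measured. On the weaned side were Epm2a, the glycogen phosphatase laforin (0.94, adjusted p = 0.0511), Ocel1 (0.81, adjusted p = 0.0615) and Psmc3ip, a cofactor of homologous recombination (1.34, adjusted p = 0.0975). Camk1g, a calcium/calmodulin-dependent kinase, differed by 0.96 and Gpx2, a glutathione peroxidase, by 1.81. The decoy interleukin 1 receptor Il1r2 differed by 1.16, the chloride channel gene Clic5 by 0.98 and Mfng, a glycosyltransferase that acts on Notch, by 0.87. Ephx4 differed by 0.85 and Igsf1 by 0.76. On the suckling side were Pde10a, a cyclic nucleotide phosphodiesterase (-0.94), the caspase-8 inhibitor gene Cflar (-0.87, with its other probe sets at -0.49 and -0.54), Ppdpf (-0.82) and Fam32a (-0.73). S1pr1, a sphingosine 1-phosphate receptor, had both group means within the background range, and its difference is not given. Dtx4, a ubiquitin ligase of the Notch pathway, differed by -0.70, the complement protease gene Masp2 by -0.67, and Pmepa1, an inhibitor of TGF-beta signalling, by -0.61. Adjusted p ranged from 0.127 to 0.313 over the genes without one of their own here.

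Genes of the cell division cycle were shifted upward in weaned mice. Of 72 measured members, 53 had a higher mean in weaned mice and the median log2 difference was 0.14 (camera with its preset correlation, adjusted p = 2.97e-05). With an estimated correlation this call was lost (adjusted p = 0.741). No member passed over all genes, while 4 passed when adjusted over the list alone, each higher in weaned mice. These were Prim1, a subunit of the DNA primase (0.73, SE 0.12), and Mcm7 (0.80, SE 0.18), Mcm3 (0.63, SE 0.14) and Mcm4 (0.56, SE 0.13) of the replicative helicase. At an unadjusted p under 0.05 there were 14 members, 13 higher and 1 lower. The proliferation marker Mki67 and other members missed both thresholds, with Mki67 at -0.07 (SE 0.18) and Ccna2, which encodes cyclin A2, at 0.36 (SE 0.21). The list mean was 4.85, 4.61 and 4.93 log2 units on weaned replicates 4, 5 and 12, and 4.56 to 4.69 on the suckling arrays. Without weaned replicate 12 the median was 0.053 and the call ended (adjusted p = 0.0536, where all alternatives ranged from 1.28e-10 to 0.741). The median was 0.26 without weaned replicate 5 and 0.083 with array weights. Weaned replicate 12 is also the weaned array with the most acinar signal, and weaned replicates 4 and 5 have the least of all 7 arrays.

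Regulators of the G1 phase showed no common shift. Of 23 measured members 12 were higher and 11 lower in mean, with a median of 0.0034, a mean of -0.0044 and a test pointing downward (camera adjusted p = 0.797). With 1 array left out the median ran from -0.039 to 0.014. Ccnd1 and Ccnd2, which encode cyclins D1 and D2, differed by 0.0034 (SE 0.13) and 0.067 (SE 0.12). Bmi1, a Polycomb gene, was the member with the smallest p (-0.33, unadjusted p = 0.0173), followed by Nr4a1 (0.38). No member passed over all genes or when adjusted over the list alone, and the cell cycle inhibitor Cdkn1a was not analysed here.

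Mitochondrial respiration genes were shifted upward in weaned mice by a small amount. Of 73 measured subunits of oxidative phosphorylation, 61 had a higher mean in weaned mice, with a median log2 difference of 0.12 (camera, adjusted p = 2.41e-06, but adjusted p = 0.741 with an estimated correlation). No subunit passed over all genes or over the list alone, and 6 had an unadjusted p under 0.05, all of them higher. The complex I subunits Ndufs6 (0.37, SE 0.11) and Ndufa7 (0.35, SE 0.12) had the smallest p. The list mean was 9.35 ± 0.06 log2 units (SD, n = 3) against 9.22 ± 0.08 (n = 4). The lowest array was suckling replicate 2 at 9.12, which is also the array with the most acinar signal. At the preset correlation the call held with the acinar covariate (0.098), with the other-cell covariate (0.092) and without suckling replicates 2 and 9 (0.075). The estimated correlation of the members was 0.26, so these fits share the limit of the first call. An exact two-sided permutation of the list mean gave p = 0.114, and another split of the arrays reached a median of 0.13.

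Other fuel pathways did not pass. Glycolysis had a median of 0.098 (15 of 21 members higher, camera adjusted p = 0.1). Pdk1, a kinase that restrains pyruvate dehydrogenase, differed by 0.85 (SE 0.22) and Aldoc, an aldolase, by 0.44 (SE 0.17). Without suckling replicate 11 the glycolysis median was 0.15 and passed (camera, adjusted p = 0.028, where alternatives ranged to 0.845). It fell to 0.036 without weaned replicate 4 and to 0.058 without suckling replicate 2 (camera, adjusted p = 0.52 and 0.367). Ldha, the lactate dehydrogenase subunit kept low in mature beta cells, differed by -0.21 (SE 0.22). Genes of fatty acid oxidation and ketogenesis had a median of 0.098 (27 of 42 higher, adjusted p = 0.319), with 4 higher and 3 lower at an unadjusted p under 0.05. Without suckling replicate 2 that median was 0.035. Among the members were Cpt1a, which controls fatty acid entry into mitochondria (0.35, SE 0.12), and Cyp4a14, with both group means at background. Cholesterol and fatty acid synthesis had a median of 0.041 (22 of 36 higher, adjusted p = 0.721), with Tm7sf2, a sterol reductase, at 0.46 and Acly, ATP citrate lyase, at -0.35. That median turned to -0.0088 without suckling replicate 9 and to -0.027 with the acinar covariate, and was 0.085 without suckling replicate 11. The tricarboxylic acid cycle list had a median of 0.034 (19 of 29 higher, adjusted p = 0.742), with Fh1, fumarase, at -0.51 (SE 0.12) and Pdha1 of pyruvate dehydrogenase at -0.27, and its median was -0.019 without weaned replicate 4 and 0.076 without suckling replicate 12. Glucose-responsive genes had a median of 0.047 (15 of 23 higher, adjusted p = 0.65), with Taldo1, transaldolase, at 0.52 (SE 0.15) and the glucose-induced gene Txnip at 0.13 (SE 0.21), and a median of 0.024 to 0.082 with 1 array left out. Cytosolic ribosomal proteins had a median of 0.044 (26 of 34 higher, adjusted p = 0.317), with Rpl14 at 0.45 and Rpl34 at -0.79, and a median of 0.019 without weaned replicate 12. None of the members of these lists passed over all genes or when adjusted over the list alone.

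**Figure D2:**
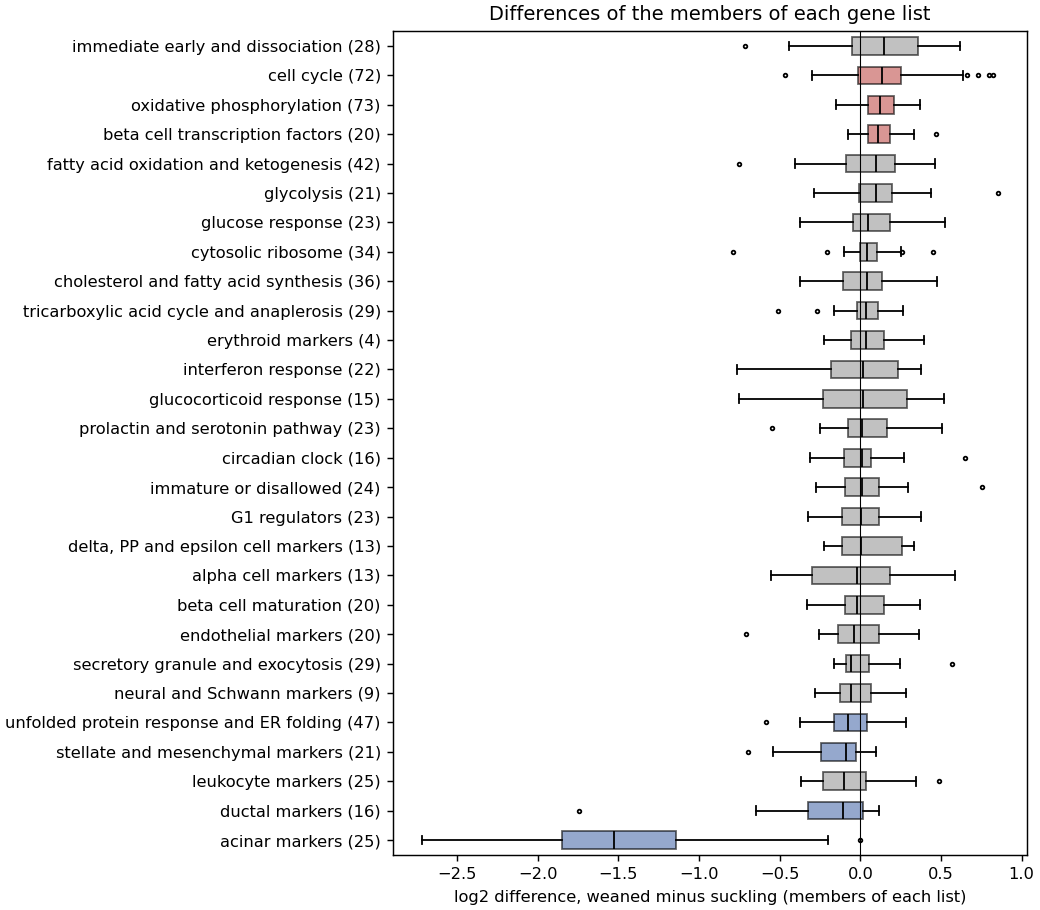
Log2 difference, weaned minus suckling, of the measured members of each gene list, with the number of members in brackets. Boxes give median and quartiles, whiskers reach 1.5 times the interquartile range and points lie beyond. Red and blue boxes passed adjusted p 0.05 by camera with its preset correlation, higher and lower in weaned mice, with medians such as 0.12 for oxidative phosphorylation and -1.53 for acinar markers. The sex-linked list is left out.

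Transcription factors of beta-cell identity were slightly higher in weaned mice. Of 20 measured members 17 had a higher mean, the median log2 difference was 0.11, and the list mean lay at 7.05 to 7.07 log2 units on the weaned arrays and 6.88 to 6.99 on the suckling arrays (camera, adjusted p = 0.0142, but adjusted p = 0.741 with an estimated correlation). Mnx1 (0.47, SE 0.13) and Pdx1, a master regulator of the pancreas and of insulin transcription (0.33, SE 0.13), had the smallest p, and no member passed over all genes or over the list alone. The lowest list means belonged to suckling replicates 2 and 9, the arrays with the most acinar signal. With the acinar level as a covariate the median was 0.099 and the call ended (adjusted p = 0.207, alternatives 0.00319 to 0.741). It also ended without weaned replicate 4 (0.10), weaned replicate 5 (0.097) or suckling replicate 9 (0.087), and without suckling replicates 2 and 9 together (0.087).

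Genes of beta-cell maturation did not shift as a group. Their median was -0.024 and their mean 0.011, with 8 of 20 higher and a test pointing downward (camera, adjusted p = 0.993). With 1 array left out the median ran from -0.045 to 0.035, that of immature or disallowed genes from -0.038 to 0.033 and that of exocytosis genes from -0.062 to -0.011. Ins2 differed by -0.023 (SE 0.14, 95% interval -0.33 to 0.28), Ucn3 by -0.033 (SE 0.13, interval -0.33 to 0.26) and the insulin gene activator Mafa by -0.18 (SE 0.13). The glucose transporter gene Slc2a2 differed by 0.047 (SE 0.11). Ppp1r1a (0.22) and Gipr, the receptor of an incretin hormone (-0.33), had the smallest p of the list. Ins1 was not analysed here. Immature or disallowed genes had a median of 0.0089 (14 of 24 higher, adjusted p = 0.889), with Dlk1 at 0.76 (SE 0.40, and 0.44 to 1.20 with 1 array left out), Rest at background in both groups, and Npy, a neuropeptide of neonatal beta cells, at -0.27 (SE 0.34). Secretory granule and exocytosis genes had a median of -0.056 (12 of 29 higher, adjusted p = 0.797), with Cplx2, a complexin of vesicle fusion, at 0.57 (SE 0.15) and Rims2 at 0.25. No member of these 3 lists passed over all genes or when adjusted over the list alone.

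The prolactin and serotonin list did not move one way, with a median of 0.012 and 13 of 23 members higher (camera, adjusted p = 0.742). The median was -0.055 without weaned replicate 12 and 0.079 without weaned replicate 4. By fry's mixed test, which asks whether a set departs from no change in either direction, this list, the glucose response list and the leukocyte list passed (adjusted p = 0.0201 each), although no member of the latter lists passed over all genes or over its list alone. Tph2, a tryptophan hydroxylase, passed when adjusted over the list alone (0.51, SE 0.12, adjusted p = 0.0425) and missed over all genes (adjusted p = 0.389). Tph1, the tryptophan hydroxylase with the brighter probe set, at 9.56 ± 0.11 log2 units in suckling mice (SD, n = 4), differed by -0.55 (SE 0.15) and missed both (adjusted p = 0.0626 and 0.511). The prolactin receptor gene Prlr was not analysed here.

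Genes of the unfolded protein response and of protein folding in the endoplasmic reticulum were slightly lower in weaned mice. Of 47 measured members 32 had a lower mean, with a median log2 difference of -0.079 (camera, adjusted p = 0.042, but adjusted p = 0.741 with an estimated correlation). Dnajb9, a co-chaperone of the endoplasmic reticulum, passed when adjusted over the list alone at 10.1 ± 0.11 log2 units (SD, n = 3) against 10.7 ± 0.05 (n = 4), a difference of -0.58 (SE 0.11, adjusted p = 0.0154), and missed over all genes (adjusted p = 0.261). No other member passed, and 4 were lower at an unadjusted p under 0.05. The median was -0.030 without weaned replicate 12, -0.068 without suckling replicate 9, -0.054 without suckling replicate 11 and -0.057 without suckling replicate 12, and the call ended in each case, as it did with arrays centred on their medians (-0.045). Acinar markers, also of secretory cells, were lower too. With the acinar covariate the median was -0.10 and with the other-cell covariate -0.12, and the call held in both at the preset correlation. Adjusted p over the alternatives ranged from 0.00391 to 0.741.

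Exocrine transcripts varied widely between arrays and were lower in weaned mice. All 25 measured acinar markers had a lower mean in weaned mice, with a median log2 difference of -1.53 (camera, adjusted p = 9.19e-08, but adjusted p = 0.741 with an estimated correlation). The mean level of the list was 3.91, 3.80 and 5.82 log2 units on weaned replicates 4, 5 and 12, and 7.40, 7.30, 4.05 and 4.96 on suckling replicates 2, 9, 11 and 12. The groups therefore overlapped, and an exact two-sided permutation test over the 35 splits of 3 against 4 arrays gave p = 0.286. No member passed over all genes or over the list alone. Cpa1, a carboxypeptidase, differed by -1.51 (SE 0.98), Prss2, a trypsinogen, by -1.36 (SE 0.89) and Pnliprp1 by -1.99 (SE 0.85). Bhlha15, a transcription factor of secretory cells, had the smallest p (-0.71, SE 0.17) and lay at 8.24 on weaned replicate 5, where the list mean was lowest. The median was -2.35 without weaned replicate 12, -0.92 without suckling replicate 2 and -0.99 without suckling replicate 9, and it turned to 0.13 without suckling replicates 2 and 9 together. With the immediate early covariate it was -0.81.

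Markers of cells other than acinar showed smaller differences. Group means of the stellate, endothelial, leukocyte and neural lists were 3.24 to 3.63 log2 units, little above the background range of 1.80 to 3.15. Small medians of these lists therefore say little about the amounts of those cells. Stellate and mesenchymal markers had a median of -0.091 (17 of 21 lower, camera adjusted p = 0.00712, but adjusted p = 0.741 with an estimated correlation). Among them were Bgn, biglycan, at -0.70 (SE 0.20), with its weaned mean at background, and Vim, vimentin, at -0.35. Without weaned replicate 4 (-0.051) or suckling replicate 2 (-0.054) that call ended, and without weaned replicate 5 the median was -0.17. It also ended with the acinar covariate (-0.058), with the other-cell covariate (-0.051) and without suckling replicates 2 and 9 together (-0.045). Ductal markers had a median of -0.11 (11 of 16 lower, adjusted p = 0.042, but adjusted p = 0.741 with an estimated correlation), with Muc1 at -0.65 and Car2 at background in both groups. The ductal call ended without weaned replicates 4 (-0.080), 5 (-0.15) or 12 (-0.12) or suckling replicates 9 (-0.19) or 12 (0.0033). It also ended above the 25th percentile of level (-0.062), above the median level (-0.062), with array weights (-0.038) and with the other-cell covariate (-0.062). It held at -0.064 without suckling replicate 2 and at -0.24 without suckling replicate 11. Alpha-cell markers had a median of -0.023 (adjusted p = 0.889), with Gcg at -0.18 (SE 0.16), Mamld1 at -0.55 (SE 0.25) and Irx2 at -0.31 (SE 0.14), which were -0.23 and -0.16 without weaned replicate 4. Delta, PP and epsilon cell markers had a median of 0.0020 (adjusted p = 0.889), with Sst at -0.21 (SE 0.17), Ppy at 0.26 (SE 0.27), Fxyd6 at 0.33 and Casr at 0.31. Endothelial markers had a median of -0.041 (adjusted p = 0.797), with Cldn5 at -0.71 and Erg at -0.26 (95% interval -0.52 to 0.0042), its weaned mean at background. Leukocyte markers had a median of -0.10 (adjusted p = 0.345), with Fcer1g at 0.48 and Ctss at -0.37 (SE 0.13), its weaned mean at background. Neural and Schwann markers had a median of -0.060 (adjusted p = 0.815), with Foxd3 at background in both groups and Ngfr at 0.29. Erythroid markers, with 4 measured, had a median of 0.034 and a test pointing downward (adjusted p = 0.993), with Alas2 at -0.23 and Bpgm at 0.40 (SE 0.36), which turned to -0.15 without weaned replicate 4. With 1 array left out the medians ran from -0.058 to 0.087 (alpha), -0.071 to 0.14 (delta, PP and epsilon), -0.092 to 0.024 (endothelial), -0.15 to -0.032 (leukocyte), -0.10 to 0.0096 (neural and Schwann) and -0.13 to 0.077 (erythroid). No member of these lists passed over all genes or when adjusted over the list alone.

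**Figure D3:**
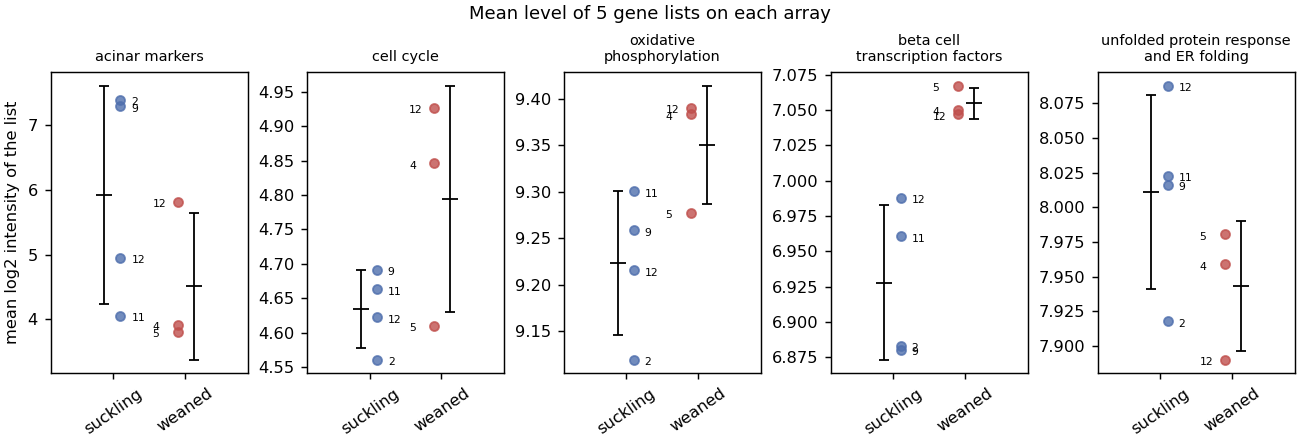
Mean log2 intensity (vertical axis) of 5 gene lists on each array, 1 point per mouse labelled with its replicate number, with mean and SD of each group. Acinar markers span 3.80 to 5.82 in weaned and 4.05 to 7.40 in suckling mice, and the cell cycle list reaches 4.93 on weaned replicate 12 and 4.61 on weaned replicate 5.

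Of 29 lists, 7 passed an adjusted p of 0.05 by camera with its preset correlation of 0.01, 3 higher and 4 lower in weaned mice. With an estimated correlation 0 lists passed by camera and 1 had an unadjusted p under 0.05. Among the 7 lists the estimate ran from 0.023 (transcription factors) and 0.028 (ductal) to 0.795 (acinar). The lowest estimates lie close to the preset 0.01, so correlation of members need not be why those calls were lost. All 7 lists share the camera adjusted p of 0.741, which the adjustment over lists levels, so it does not rank them. By fry's directional test 0 passed and 2 had an unadjusted p under 0.05. By an exact permutation test of the list mean 0 lists had an unadjusted p under 0.05, where the smallest p that 35 splits allow is 0.0286. Adjusted over 29 lists that smallest p passes only if many lists reach it together, so the adjusted values of this test say nothing about the calls.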

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

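In 4 of 125 sets of suckling values, 1 of the 4 arrays lay far from the others by Dixon's ratio of the gap to the range, which chance gives in about 1 of 20 sets. Mfng was 3.22 log2 units on suckling replicate 9 and 3.62 to 3.68 on the other suckling arrays. Fam32a was 7.90 on suckling replicate 9 and 7.61 to 7.65 on the others. Acly was 10.8 on suckling replicate 12 and 10.7 on the others. Mamld1, an alpha-cell marker, was 5.94 on suckling replicate 2 and 5.43 to 5.48 on the others. The 3 weaned arrays are too few for this comparison.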

How the results depend on the processing

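Settings chosen after the data were seen are the fit on all probe sets, the exact permutation of list means and the fit without suckling replicates 2 and 9. The permutation was planned only for the lists of other cells and the immediate early list. Of 125 named genes and lists with a test, 10 passed in the fit reported. Over their 200 alternatives they kept direction and passed in 132, kept direction and missed in 64 (the exact permutation of each of 7 lists among them, which the number of splits all but kept from passing) and changed direction in 4. Of the other results, 8 passed under at least 1 alternative, Fggy under 7 (adjusted p 0.00344 to 0.9 over all its alternatives). The count of genes past the threshold, 3 as reported, was 9 with an intensity trend and robust prior (5 higher, 4 lower), 5 after quantile normalization (2 higher), 6 with arrays centred on their medians (3 higher), 6 above the 25th percentile of level (3 higher), 8 above the median level (5 higher) and 5 with the mean of a gene's probe sets (2 higher). It was 7 at an adjusted p of 0.1 (4 higher), and 217 at an unadjusted p under 0.05 with a 1.5-fold difference (125 higher, 92 lower). With the other-cell covariate 0 genes were higher by limma (549 higher and 611 lower at an unadjusted p under 0.05, against 875 and 637 as reported and 568 and 579 with the acinar covariate, so the excess of higher genes was absent with either), while Cstdc1 itself was at 1.54 against 1.48 as reported, and with all probe sets 0 were higher and 3 probe sets, of Hapln4 and Fggy, were lower. Leaving out 1 array gave 1 to 3 genes, 0 to 1 higher and 1 to 2 lower, and leaving out suckling replicates 2 and 9 gave 0, with 0 higher and 0 lower, where fewer arrays lower the power. Of 96 named genes, 36 moved by over 1.5 times or turned with 1 array left out, 7 of them turned, and none of the 36 had passed. The median of the transcription factor list, 0.11 as reported, missed the threshold above the median level (0.13), with the acinar covariate (0.099), with the other-cell covariate (0.087) and without suckling replicates 2 and 9 (0.087), and ranged from 0.087 to 0.13 with 1 array left out, passing in 4 of 7 such fits. The cell cycle median ranged from 0.053 to 0.26 with 1 array left out (passing in 6 of 7; 0.083 with array weights), that of oxidative phosphorylation from 0.088 to 0.16 (7 of 7) and that of glycolysis, not past as reported, from 0.036 to 0.15 (1 of 7). The unfolded protein response list missed the threshold with centred arrays (-0.045) and ranged from -0.11 to -0.030 with 1 array left out (passing in 3 of 7). With an estimated correlation, by fry's directional test and by exact permutation of list means, which leave the medians at 0.11 (transcription factors), 0.14 (cell cycle), 0.12 (oxidative phosphorylation) and -0.079 (unfolded protein response), 0 lists passed by the former 2 tests and 1, 2 and 0 had an unadjusted p under 0.05, while 3 lists passed by fry's mixed test. Camera with an estimated correlation, fry and the permutation all allow for correlated members, and the latter 2 do not compare a list with other genes. The acinar median turned to 0.12 with its own mean as a covariate and to 0.32 with the other-cell mean, which contain the same genes, and to 0.13 without suckling replicates 2 and 9, the arrays with most acinar signal, and was -0.81 with the immediate early covariate. The ductal median ranged from -0.24 to 0.0033 with 1 array left out, turning without suckling replicate 12. For the other moves the cause was not tested. No paired analysis was possible because the groups share only 1 replicate number, 12, and nothing in the labels says that a number links mice. Signal over background limits genes such as Cstdc1, which lies at the 34.9th percentile of level and drops out above the median level.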

Other observations

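Of 5 secondary lists, covering stress of dissociation, hormones, the clock, interferon and sex, none passed the list test. Hsph1, a heat-shock protein of the cytosol, was 7.54 ± 0.19 log2 units in weaned mice (SD, n = 3) and 8.26 ± 0.11 in suckling mice (n = 4), a difference of -0.72 that passed limma when adjusted over the immediate early and dissociation list alone (adjusted p = 0.00736) and missed over all genes (adjusted p = 0.225). The list itself had a median of 0.15 with 17 of 28 members higher and did not pass (camera, adjusted p = 0.65), and its median was 0.00020 without weaned replicate 5. Glucocorticoid response genes had a median of 0.018 and a test pointing downward (adjusted p = 0.993), with the glucocorticoid-induced gene Fkbp5 at 0.52 (SE 0.18) and Nfkbia, an inhibitor of NF-kappa-B, at 0.30 (SE 0.12). Circadian clock genes had a median of 0.011 (adjusted p = 0.889), with the clock output repressor gene Nfil3 at 0.65 (SE 0.20) and Nr1d1 at -0.31 (SE 0.21). Interferon response genes had a median of 0.019 and a test pointing downward (adjusted p = 0.993), with Ifi27l2a at -0.77 (SE 0.19) and the immunoproteasome subunit Psmb9 at 0.38 (SE 0.15). The 4 measured sex-linked genes had a median of -0.62 (adjusted p = 0.742), with Eif2s3y at -0.97 (SE 1.53) and Uty at -0.60 (SE 1.19). With 1 array left out the medians ran from -0.060 to 0.13 (glucocorticoid), -0.050 to 0.060 (circadian), -0.071 to 0.11 (interferon) and -1.65 to 0.12 (sex-linked). None of these members besides Hsph1 passed when adjusted over its list alone.

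Chosen after the results were seen were the comparison of replication with mitotic genes, the correlation among acinar genes, the count of neighbouring genes and the splits without sex-linked genes. Deviations of acinar genes from their group means had a median pairwise correlation of 0.94 over the 7 arrays, and as large a difference of the list mean came from 10 of 35 splits of the arrays (real -1.42, highest other 2.66). Ctrb1, the acinar enzyme of the list with the brightest probe set and chosen after its values were seen, spanned 4.18 to 8.47 log2 units on the weaned arrays and 5.16 to 10.3 on the suckling arrays, although the sort kept reporter-positive cells. None of the 25 measured acinar genes is in another list, and 4 lay above the median gene on weaned replicate 5.

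Within the cell cycle list, 28 of 31 genes of DNA replication were higher in weaned mice with a median of 0.22, against 25 of 41 mitotic genes with a median of 0.054. The difference of their means, 0.22, was reached by 4 of 35 splits (exact two-sided p = 0.114), which leaves a shift limited to replication genes open as a hypothesis. The tables argue against less acinar RNA as the whole cause, because the list median was 0.15 with the acinar covariate. The list median was 0.14 with the other-cell covariate, but that covariate includes the acinar genes and follows them across the arrays. This second fit therefore cannot tell RNA of other cells apart from acinar RNA, and less RNA of other cells stays open. Chance could not be excluded, since 10 of 35 splits gave a median as far from 0 (real 0.14, highest other 0.23) and 5 gave as many lists past the threshold (real 7, highest other 9). The weight of a single array is also open, since the median without weaned replicate 12 was 0.053. The medians with 1 array left out had an SD of 0.066. The description codes cannot be told apart from weaning, because 0 groups hold both. More replicating beta cells after weaning therefore remains a hypothesis. The replication genes had an exact two-sided p of 0.0571, with medians of 0.32 with the acinar covariate and 0.31 without suckling replicates 2 and 9. They were grouped after the results of the same arrays were seen, so these values are no independent support. The mitotic genes had an exact two-sided p of 0.457, with medians of 0.049 and -0.0025 in the same 2 fits. Neither they nor Mki67 (-0.07, SE 0.18) showed a clear direction.

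Hapln4, AI506816 and Cstdc1 passed the threshold, and Fggy missed it narrowly (adjusted p = 0.0511, range 0.00344 to 0.9 over its alternatives). For the count of 2 lower genes 1 of 35 splits, the real one, gave as many (real 2, highest other 0), which excludes chance only at the smallest share that 35 splits allow (0.0286) and for 1 of several counts tried, and AI506816 passed in 1 of 7 fits with an array left out, while 3 splits gave as many higher genes (real 1, highest other 3) and 2 as many genes in all (real 3, highest other 3). The other split with 3 genes, weaned replicate 4 with suckling replicates 9 and 12, called Eif2s3y, Kdm5d and Uty, and with sex-linked genes left out 1 split, the real one, gave as many (real 3, highest other 0). A fault of 1 probe set is argued against for Fggy by 4 of its 5 probe sets, which differed by -2.04 to -2.42, although 2 of these differences are bounds because the weaned means lie at background. Differences in sequence between families of outbred mice may also set single genes apart, and 8 neighbouring pairs among the 100 genes with the smallest p, where random sets gave a median of 5 and 12.9% gave as many, leave that and an effect of weaning open.

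Weaned replicate 12 was low both in Xist, at 2.52 log2 units, and in the Y-linked genes Eif2s3y, Uty and Kdm5d, at 1.80, 2.05 and 2.92. Each of the other 6 arrays had either Xist of 7.70 to 8.16 or Eif2s3y of 6.43 to 7.12. Both groups held arrays of each kind, and no fit here had sex as a covariate. Weaned replicate 12 was not an outlier by correlation, since 4 arrays had a lower median correlation with the others than its 0.987. These medians spanned only 0.984 to 0.988 and no measure of RNA quality was examined, so poor RNA stays open. A single X chromosome without a Y is a candidate explanation, since the mean of 4 genes that escape X inactivation (Kdm6a, Kdm5c, Eif2s3x and Ddx3x) was 7.45, below 7.95 to 8.06 on the 3 arrays with high Xist and next to 7.50 to 7.79 on the arrays with Y-linked signal. The labels give no sex, loss of Xist expression by other means was not tested, and without this mouse the calls of the cell cycle (median 0.053), unfolded protein response (-0.030) and ductal (-0.12) lists and of Cstdc1 (1.43) end, all but the first also without others.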
